A study of Mus musculus with 12 samples.

How the data were processed

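RNA sequencing libraries of medullary thymic epithelial cells were analysed: 6 of MHC class II high cells and 6 of MHC class II low cells, from Psmb11-deficient and WT mice. Per the labels, RNA was extracted with TRIzol and an RNeasy kit and libraries were made with a TruSeq RNA kit. The cortical epithelial cells and thymocyte subsets that the series also names were not analysed here. For each library the authors deposited a table of read counts per gene, as whole numbers with no normalisation, in a column that ignores the strand and a column for each strand. The authors also deposited expected counts per gene, the estimated counts of RSEM, and TPM. The submitters' processing notes list CASAVA 1.8.2, STAR 2.5.1b and RSEM 1.2.28 and the build name GRCh38; the gene identifiers are mouse identifiers, and the annotation is not given in the sources used here. The strand columns held equal shares of the reads, so the column that ignores the strand was used. The RSEM totals were between 0.507 and 0.535 of the read totals.

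Of 50600 gene identifiers 50376 were matched to symbols by stable identifier in GENCODE M21, and 45737 of them carried the same version. Coordinates are those of GENCODE M21 on GRCm38. Symbols that 136 identifiers share were kept apart by identifier. Of the 283 genes on the lists, 1 had no match, an Aire-dependent antigen.

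Cell type was taken from the labels, which name the same one in every field. Genotype was taken from the labels only where title, source name and strain name the same one. The 4 libraries where they conflict (replicates 1 and 3 by title in each cell type) have no genotype in the main comparisons. They have one only in the alternatives and values that take genotype from the title or from the source name. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr (count minimum 10, total minimum 15), counts were scaled by TMM and tested with the edgeR quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. mTEC hi and mTEC lo were compared over 12 libraries with genotype class as a covariate. Psmb11-deficient and WT libraries were compared within each cell type in a model of 4 groups over 8 libraries with 4 residual degrees of freedom, and the interaction was a contrast of the same model. The square root of the common dispersion was 0.115 over 12 libraries and 0.125 over 8. CPM values are scaled by TMM. The standard error of a log2 fold change is its size divided by the square root of the F statistic.

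The 25 gene lists and the rule for named genes were fixed before the data were examined. For mTEC hi against mTEC lo the rule takes the 5 largest rises and the 5 largest falls among called genes with a mean of at least 10 CPM and the same sign in all 6 pairs with matching titles, leaving out predicted genes. It adds the 2 called genes of largest change from each list, or the gene of lowest p where none is called. For the genotypes it takes called genes with a mean of at least 2 CPM and groups that do not overlap, makes up 5 per direction by the lowest p, and adds the gene of lowest p from each list. For the interaction it takes the 5 lowest p, and Psmb11 is always named. Some genes that the rule takes are not reported here. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. For fry only the directional test is given, and its test without regard to direction is not reported here. A floor of 3 reads over the group was used where a gene had no read in a cell type. For the breadth of expression each library was thinned to 38791960 reads, genes with at least 5 reads were counted, and the means were compared by an exact permutation test.

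Total gene reads ranged from 38791960 to 86793594. The fits were tested on simulated data of the same size and depth, with 50 genes changed at each fold. The changed genes had a mean of at least 2 CPM, and all folds were simulated together. For mTEC hi against mTEC lo 92% of 1.5-fold and 100% of 2-fold changes were recovered. For the genotypes in mTEC hi 40% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes were recovered, and in mTEC lo 50%, 90% and 100%. Intervals from reads cover counting error only.

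The alternatives were RLE size factors, DESeq2, no filter, RSEM counts, leaving out each library (for counts of genes), genotype from the title or from the source name for all libraries, the number in the title as a replicate block, the 8 libraries with undisputed genotype, a minimum change of 1.5-fold, each cell type fitted alone, other read minimums, an estimated correlation and fry. Scaling by library size alone, leaving out the libraries of title number 1, the replicate block within each cell type, the list tests between genotypes with each library left out and the list tests under further scalings were added after the data were seen. The cTEC list without Psmb11 was also tested after the data were seen. The strand columns and TPM entered no test.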

Results

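Gene expression was measured by RNA sequencing of polyadenylated RNA in medullary thymic epithelial cells (mTECs), which display the body's own antigens to developing T cells. The cells came from mice 6 to 8 weeks old, either wild type (WT) or lacking Psmb11, the gene of the thymus-specific proteasome subunit beta5t. Cells with high surface MHC class II (mTEC hi) and cells with low MHC class II (mTEC lo) were profiled in 6 libraries each. In 8 libraries every label gave the same genotype, which left 2 Psmb11-deficient and 2 WT libraries per cell type. In the other 4 libraries the title named the opposite genotype from the source name and strain. These entered the comparison of the cell types and no main comparison of genotypes. They were given a genotype only where it is stated to come from the title or from the source name. Reads assigned to genes ranged from 38791960 to 86793594 per library. The labels do not say whether libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. No libraries of the same cell type agreed within sampling noise: the lowest chi-square per gene between any 2 of them was 7.77.

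Psmb11, on chromosome 14 (54621433 to 54629556 in GRCm38, GENCODE M21), was read out first, because it is the gene the mice were made to lack. In mTEC hi its level was 0.85 and 1.30 CPM (read counts normalised for library size) in the Psmb11-deficient libraries and 10.29 and 7.53 CPM in the WT libraries. In mTEC lo it was 1.63 and 1.17 CPM in the Psmb11-deficient libraries and 12.20 and 7.51 CPM in the WT libraries. In the libraries with conflicting labels it was 8.15 CPM (mTEC hi) and 7.10 CPM (mTEC lo) where the title said WT, and 1.12 CPM and 1.26 CPM where the title said knockout. Across all 12 libraries the lowest value under a WT title was 4.36 times the highest value under a knockout title. Between mTEC hi and mTEC lo the log2 fold change of Psmb11 was -0.11, which did not pass the threshold. These values were not used to place any library in a group.

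**Figure D1:**
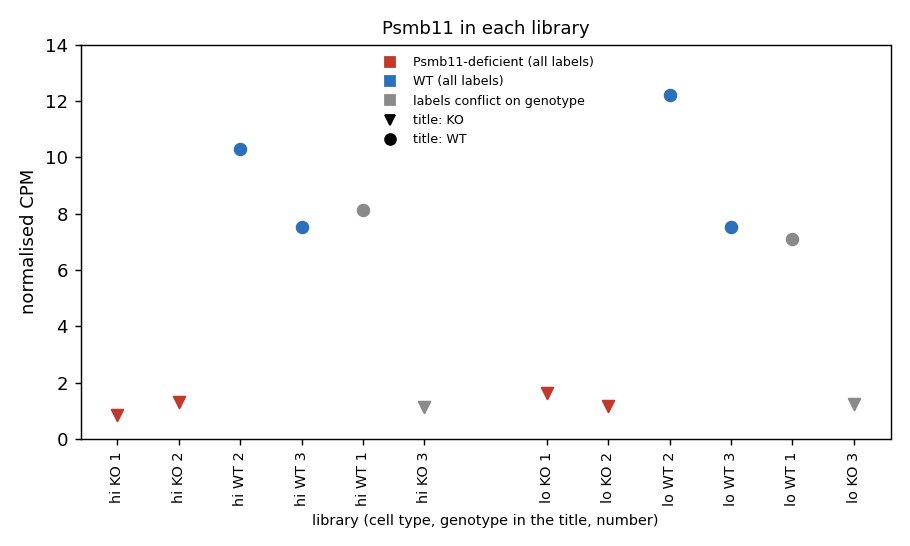
Psmb11 level (vertical axis, normalised CPM) in each of the 12 libraries (horizontal axis, named by cell type and by the genotype and number in the title). Colour gives the genotype where all labels name the same one, and grey marks the 4 libraries whose labels conflict; each point is 1 library, and the points under knockout titles lie between 0.846 and 1.63 CPM.

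The first comparison asked which genes separate mTEC hi from mTEC lo. In mTEC hi, Aire, the regulator that switches on tissue-restricted antigens in the thymus, stood at 1977 ± 185 CPM against 17.6 ± 5.35 CPM in mTEC lo (SD, n = 6 each), a log2 fold change of 6.84. The largest rises by the rule for named genes were those of Lefty2 (a signalling inhibitor of the TGF-beta family, log2 fold change 8.85), Calcr (the calcitonin receptor, 8.69), the kallikrein pseudogene Klk2-ps (8.30), Csn1s2a (a milk casein, 8.17) and Madcam1 (an adhesion molecule of mucosal vessels, 8.09). By the same rule, the largest fall was that of Gas1, a Hedgehog co-receptor (658 ± 79.9 CPM in mTEC lo against 16.4 ± 2.23 CPM in mTEC hi). Next came Mgp, matrix Gla protein (log2 fold change -4.73), Fst, the activin antagonist follistatin (-4.63), Tril (-4.63) and Boc, another Hedgehog co-receptor (-4.53). The rule took only genes with the same direction in all 6 pairs of mTEC hi and mTEC lo libraries with matching titles. The standard errors of the 10 fold changes lay between 0.0532 (Boc) and 0.237 (Calcr).

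Tissue-restricted antigens rose as groups. Of the 10 measured Aire-dependent antigens, all 10 rose (median log2 fold change 5.83, camera adjusted p = 2.12e-06; adjusted p = 0.0101 with an estimated correlation). Their summed level was 1113 ± 91.1 CPM in mTEC hi and 41.5 ± 9.12 CPM in mTEC lo. Rbp3, a retinal protein, had no read in any mTEC lo library and was at least 104-fold higher in mTEC hi against a floor of 3 reads over the 6 libraries. Mup1 also had no read in mTEC lo, and with both genes at this bound the median of the list was 5.32. Of the 11 Fezf2-dependent antigens, 10 rose and 1 fell (median 3.50, adjusted p = 1.14e-05; adjusted p = 0.0223 with an estimated correlation). Among them Coch, an inner ear protein, was at 90.3 ± 4.53 CPM against 0.99 ± 0.26 CPM, and Mup4, a urinary protein, rose by 7.35.

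Of the 10 genes of mature mTECs, 8 rose and 1 fell (median 2.52, adjusted p = 2.5e-09; adjusted p = 0.00902 with an estimated correlation). Besides Aire, the T cell costimulator Cd86 rose from 1.06 ± 0.21 CPM to 33.3 ± 3.18 CPM. The MHC class II list covers the surface mark the cells were sorted on, so its direction is not independent evidence. In it 8 of 9 genes rose (median 1.23, adjusted p = 3.05e-05; adjusted p = 0.248 with an estimated correlation), with H2-Ob (2.95) and H2-Oa (2.37) changing most. All 16 cell cycle genes rose (median 3.13, adjusted p = 2.5e-09; adjusted p = 0.135 with an estimated correlation), among them the mitotic kinases Bub1 (4.03) and Cdk1 (3.67). In the list of TNF receptor and NF-kB signalling 9 of 14 genes rose and 3 fell (median 0.98, adjusted p = 0.0208; adjusted p = 0.367 with an estimated correlation). The costimulatory ligand gene Icosl (3.11) and Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (3.01), rose most.

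The genes that were lower in mTEC hi included those of immature mTECs, tuft cells, interferon response and early stress. Of 10 genes of immature or Ccl21-producing mTECs, 9 fell (median -2.35, adjusted p = 1.15e-11; adjusted p = 0.0246 with an estimated correlation). Ccl21a, a chemokine that draws thymocytes into the medulla, was at 3813 ± 476 CPM in mTEC lo and 203.5 ± 16.1 CPM in mTEC hi, and the glycoprotein gene Pdpn fell by 3.05 on the log2 scale. All 13 genes of thymic tuft cells, chemosensory epithelial cells, fell (median -2.44, adjusted p = 7.37e-07; adjusted p = 0.277 with an estimated correlation), among them the cytokine Il25 (-2.98) and Alox5ap of leukotriene synthesis (-3.30). Of 11 interferon response genes, 10 fell (median -1.71, adjusted p = 1.39e-10; adjusted p = 0.0223 with an estimated correlation), Ifit3 (-3.66) and Ifi44 (-3.28) most. All 10 immediate early genes, which tissue dissociation can induce, fell (median -1.76, adjusted p = 1.67e-06; adjusted p = 0.277 with an estimated correlation). Fos was at 5821 ± 533 CPM in mTEC lo against 1052 ± 142 CPM in mTEC hi, and Atf3 fell by 2.71. Of 10 heat shock genes 5 fell and 2 rose (median -0.62, adjusted p = 0.0415; adjusted p = 0.506 with an estimated correlation), with Dnajb1 (-1.76) and Hspa1a (-1.68) changing most.

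Markers of blood cells that a sorted preparation could hold were also measured. All 6 B cell genes were higher in mTEC hi (median 4.71, adjusted p = 0.019; adjusted p = 0.277 with an estimated correlation), as were all 11 genes of dendritic cells and macrophages (median 2.92, adjusted p = 0.00273; adjusted p = 0.284 with an estimated correlation). Examples were Blk (14.6 ± 0.76 CPM against 0.49 ± 0.17 CPM), Ms4a1 (4.88), Flt3 (5.29) and Adgre1 (20.2 ± 2.19 CPM against 0.96 ± 0.40 CPM). All 6 erythroid genes rose one by one, among them Alas2 (3.42), but the list missed the threshold (adjusted p = 0.216). In the thymocyte list 8 of 14 genes rose and none fell (adjusted p = 0.52 for the list), with Tcf7 at 109.2 ± 13.4 CPM against 21.3 ± 6.34 CPM and Ptcra at 1.29 ± 0.18 CPM against 0.15 ± 0.11 CPM.

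The other lists missed the threshold for mTEC hi against mTEC lo, although single members changed. Among chemokines 8 rose and 4 fell (adjusted p = 0.188), with Xcl1 (7.03) and Ccl22 (5.16) rising most. Among genes of cortical epithelial cells (cTECs) 5 rose and 4 fell (adjusted p = 0.52), with the protease gene Ctsl (-3.08) and Ackr4 (-2.92) changing most, and the median (0.06) and the test differed in sign. Among ER stress genes 6 rose and 3 fell (adjusted p = 0.353), Chac1 (2.77) and Trib3 (2.76) most; among cornified or post-Aire genes 4 rose and 2 fell (adjusted p = 0.878), Krt77 (1.59) and Krt1 (1.46) most. In the fibroblast and pericyte list 3 rose and 4 fell (adjusted p = 0.977), with Pdgfrb (3.49) and Col1a1 (3.34) rising most, and its median (-0.72) and mean (0.14) differed in sign. In the sex-linked list 1 rose and 4 fell (adjusted p = 0.565), with Uty (-0.77) and Eif2s3y (-0.61) changing most. In 4 lists the median also turned positive under scaling by library size alone. These were the 26S proteasome (4 rose, 17 fell of 32; adjusted p = 0.42; Psma6 at 0.67, Psmd7 at -0.52), the immunoproteasome with MHC class I presentation (4 rose, 8 fell; adjusted p = 0.603; Psme2 at 1.13, Psmb10 at 0.83), NRF2 and oxidative stress (5 rose, 5 fell; adjusted p = 0.977; Srxn1 at 2.34, Slc7a11 at -1.75) and endothelial cells (3 fell, adjusted p = 0.639; Tek at -0.72). The endothelial gene Emcn (-0.61, adjusted p = 0.0134) lost its call with RSEM counts (adjusted p = 0.287) and with scaling by library size alone (adjusted p = 0.172).

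**Figure D2:**
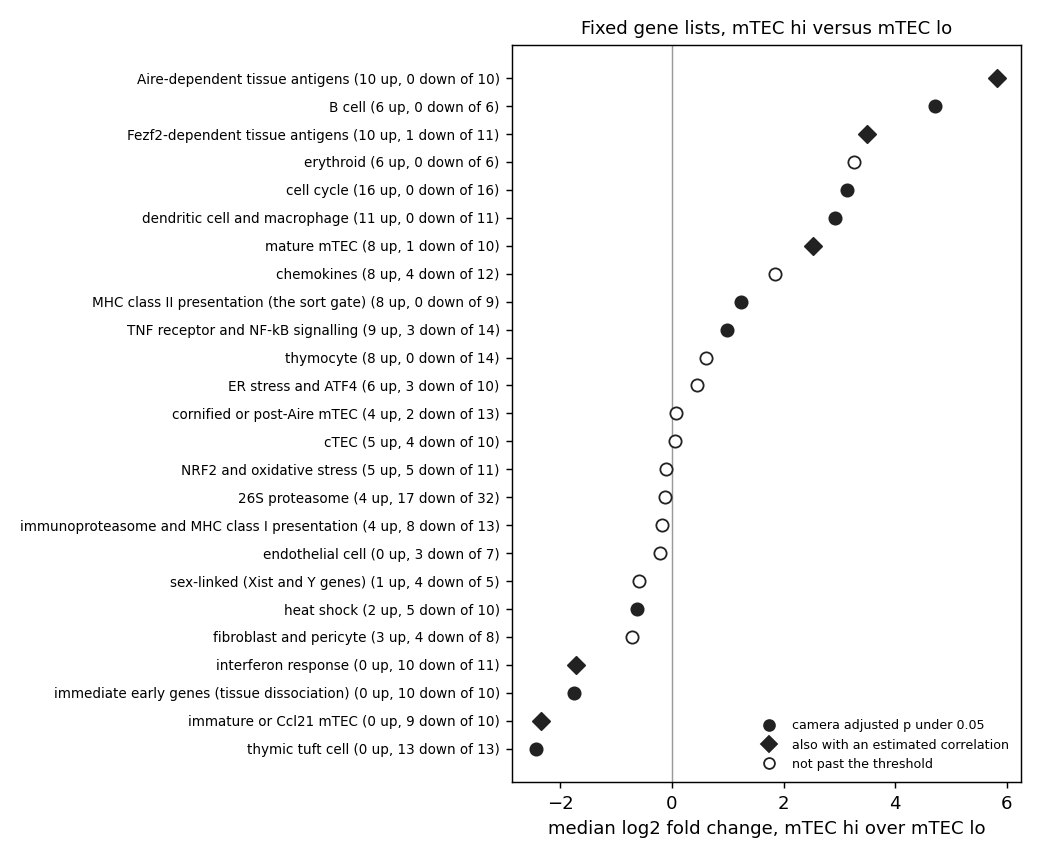
Median log2 fold change of mTEC hi over mTEC lo (horizontal axis) for each of the 25 fixed gene lists (vertical axis, with the number of members that rose and fell). Filled symbols passed camera and diamonds also passed with an estimated correlation; the Aire-dependent antigens lie farthest to the right at 5.83 (5.32 with the genes that had no read in mTEC lo at their bound) and the tuft cell genes farthest to the left at -2.44.

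By edgeR, 19649 of 23923 tested genes (82.1%) differed at a false discovery rate of 0.05, of which 10569 were higher and 9080 lower in mTEC hi. Changes of at least 2-fold were 8014 up and 3011 down, and changes of at least 8-fold were 4318 up and 267 down. Normalisation sets the balance: 53.8% of the called genes were higher in mTEC hi under TMM and 67% under scaling by library size alone, where the median of all genes moved from 0.08 to 0.37. Against a minimum change of 1.5-fold 12958 genes passed. Of the 25 lists, 13 passed camera with a preset correlation of 0.01, and 5 of these held with an estimated correlation: mature mTEC, immature or Ccl21 mTEC, Aire-dependent antigens, Fezf2-dependent antigens and interferon response.

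The breadth of expression was compared next, since wide expression of tissue genes is a known property of mature mTECs. After each library was thinned to 38791960 reads, 26965 ± 222 genes had at least 5 reads in mTEC hi and 21180 ± 248 genes in mTEC lo (SD, n = 6 each). The difference of 5784 genes, an excess of 27.3%, had an exact two-sided permutation p = 0.00216, the smallest that 6 against 6 libraries allow. Among protein-coding genes the numbers were 18930 ± 42.7 and 16274 ± 45.1. Reads in no annotated gene, examined after the data were seen, made up 14.8 ± 1.04% of mTEC hi and 9.66 ± 1.35% of mTEC lo libraries (exact two-sided permutation p = 0.00216), and whether this difference between the libraries adds to the count of genes was not tested. Between genotypes the ranges were 26718 to 27210 genes in Psmb11-deficient and 26796 to 26940 genes in WT mTEC hi libraries, and 20932 to 21232 genes and 21220 to 21401 genes in mTEC lo.

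**Figure D3:**
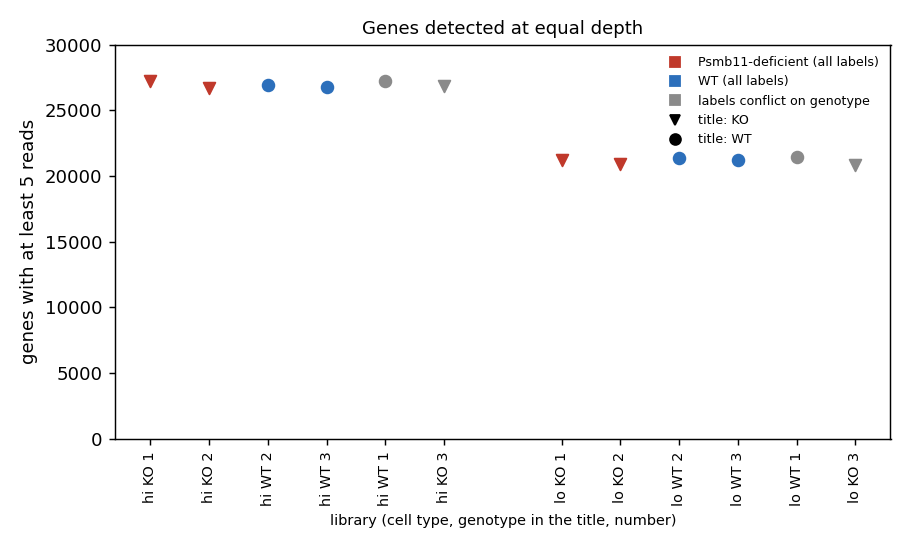
Number of genes with at least 5 reads at equal depth (vertical axis, from 0) in each library (horizontal axis, named by cell type and by the genotype and number in the title). Each point is 1 library; the mTEC hi libraries average 26965 genes and the mTEC lo libraries 21180 genes.

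The next comparison asked which genes differ between Psmb11-deficient and WT mTEC hi, with 2 libraries each. Psmb11 fell (log2 fold change -3.07, SE 0.306, edgeR adjusted p = 0.00457) and no other gene passed. The rule for named genes also gives the lowest p-values as values only, none past the threshold: the pseudogenes Tpt1-ps3 (0.56), Rps6-ps4 (1.45) and Rpl14-ps1 (0.99), and Dtx4 (0.49) above WT, and the imprinted gene Grb10 (-0.53), Xist (-0.51), Il25 (-1.03) and Tet2 (-0.39) below, all at an adjusted p of 1. Xist, the RNA that coats the inactive X chromosome of female cells, was at 708 CPM and 802.5 CPM in the Psmb11-deficient libraries and at 1160 CPM and 1001 CPM in the WT libraries. With conflicting labels it was at 1062 CPM under the knockout title and at 1047 CPM under the WT title. The other 4 genes of the sex-linked list, which are Y genes, were above WT in both cell types. None of them passed the threshold, and a difference in the share of male cells was not tested. At an unadjusted p under 0.05 there were 918 genes (3.45%). DESeq2 called 3 genes: Psmb11, Grb10 and Xist. Without Psmb11-deficient replicate 1 or without WT replicate 2, no gene passed, and Psmb11 was at -2.77 and -2.82 there (adjusted p = 0.448 and 0.194); without Psmb11-deficient replicate 2, 2 genes passed.

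By camera, 11 lists passed in mTEC hi, and none of them held with an estimated correlation or with the directional test of fry. The thymocyte genes were higher in the Psmb11-deficient libraries, with all 14 above WT (median log2 fold change 0.87, adjusted p = 3.83e-13; adjusted p = 0.352 with an estimated correlation) and Dntt at 1.23. All 10 heat shock genes were below WT (median -0.20, adjusted p = 1.56e-08; adjusted p = 0.352 with an estimated correlation), with Hsph1 at -0.48. Of 13 tuft cell genes 12 were below WT (median -0.32, adjusted p = 2.49e-08; adjusted p = 0.352 with an estimated correlation). The tuft cell call rested on WT replicate 3, where the list mean was 4.87 against 4.51 in the other WT library and 4.33 and 4.53 in the Psmb11-deficient libraries; without it the median was -0.01 and the adjusted p was 0.509. All 32 genes of the 26S proteasome were above WT by a small amount (median 0.10), with Psmb4 at 0.16. The adjusted p was 2.93e-05 by camera and 0.475 with an estimated correlation. By title, the list mean was 6.756 under knockout and 6.672 under WT in number 1, and 6.757 and 6.674 in number 2. It was reversed in number 3, at 6.656 and 6.666. Numbers 1 and 3 use the libraries whose labels conflict. Reads in no annotated gene made up 14.2% and 13.0% of the Psmb11-deficient and 15.8% and 15.3% of the WT libraries. Whether this difference moved the list was not tested. All 10 immediate early genes were below WT (median -0.18, adjusted p = 6.42e-05; adjusted p = 0.475 with an estimated correlation), with Jun at -0.27. The remaining calls were chemokines (10 of 12 above, adjusted p = 0.0137, Ccl22 at 0.43), Aire-dependent antigens (9 of 10 above, adjusted p = 0.0173, Csn1s1 at 0.28), NRF2 and oxidative stress (10 of 11 above, adjusted p = 0.0336, Prdx1 at 0.20), immature mTECs (8 of 10 above, adjusted p = 0.041, Pdpn at 0.35), NF-kB signalling (11 of 14 below, adjusted p = 0.037, Traf3 at -0.17) and cTEC genes (7 of 10 below, adjusted p = 0.0125). With an estimated correlation their adjusted p was 0.352, 0.352, 0.596, 0.475, 0.475 and 0.352, in that order. The cTEC list contains Psmb11, and without it the list missed the threshold (adjusted p = 0.884). The lists that missed the threshold had adjusted p of 0.171 (interferon response) or more. They included mature mTEC (Ubd at 0.14), MHC class II (H2-Ob at -0.19), cell cycle (Birc5 at 0.30) and the immunoproteasome with MHC class I presentation (Nlrc5 at -0.24). Thymocyte and heat shock genes also differed between libraries by the number in the title: the Psmb11-deficient libraries carry numbers 1 and 2, the WT libraries numbers 2 and 3, and within number 2 the difference of the list mean was 0.17 for thymocyte genes and -0.09 for heat shock genes. Without Psmb11-deficient replicate 1 the thymocyte median fell to 0.19 and the list missed the threshold (adjusted p = 0.0782), and so did the immediate early genes (median 0.01, adjusted p = 0.952), which also missed it without WT replicate 3 (adjusted p = 0.176). With each of the 8 libraries left out in turn, the heat shock and 26S proteasome lists passed every time, and each of the 6 lists from chemokines to cTEC genes missed the threshold in 3 or 4 of the 8 fits. In 2 of these fits 1 or 2 lists passed that had not passed with all libraries.

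In mTEC lo, the same comparison of 2 Psmb11-deficient and 2 WT libraries gave 4 genes past the threshold. Psmb11 fell (log2 fold change -2.81, SE 0.295, adjusted p = 0.00814). Hsph1, a heat shock protein of the Hsp110 family, also fell (-0.97, SE 0.12, adjusted p = 0.0168), from 361 CPM and 383 CPM in WT to 177 CPM and 205 CPM in the Psmb11-deficient libraries. The other 2 genes had few reads. The hemoglobin gene Hba-a1 had 78 reads in the Psmb11-deficient and 1 read in the WT libraries, a ratio of 70.8 at equal depth (exact binomial 95% interval 12.3 to 2830, counting error only). The neutrophil gene Retnlg had 1 read and 95 reads, a ratio of 0.00956 (interval 0.00024 to 0.0546). Below the threshold, the lowest p-values above WT were those of Tm4sf5 (1.01, adjusted p = 0.0578), the T cell surface gene Thy1 (1.11), Tff3 (1.17), Timp1 (0.55) and the T cell factor Tcf7 (0.82), and below WT those of Xist (-0.70, adjusted p = 0.0697), Nktr (-0.61) and Ttn (-0.63). At an unadjusted p under 0.05 there were 3010 genes (11.3%). The count of genes past the threshold rested on single libraries: it was 263 without Psmb11-deficient replicate 1, 323 without Psmb11-deficient replicate 2, 18 without WT replicate 2 and 22 without WT replicate 3, and it was 1 without WT mTEC hi replicate 2 and 1 without WT mTEC hi replicate 3, which share the estimate of the spread. DESeq2 called 158 genes. With genotype from the title for all libraries Hsph1 was at -0.76 (adjusted p = 0.109), Hba-a1 at 1.67 (adjusted p = 0.369) and Retnlg at -3.74 (adjusted p = 0.109), none past the threshold. Hsph1 did pass once the title number was added to that fit as a replicate block, as given with the processing below.

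By camera, 9 lists passed in mTEC lo, and none held with an estimated correlation or with the directional test of fry. Psmb11-deficient replicate 2 had the highest share of mitochondrial reads, with 3.22% against 2.11% to 2.71% in the other mTEC lo libraries. Whether this bears on the lists was not tested. All 14 thymocyte genes were above WT (median log2 fold change 0.92, adjusted p = 4.09e-13; adjusted p = 0.265 with an estimated correlation). All 10 heat shock genes were below WT (median -0.36, adjusted p = 1.06e-10; adjusted p = 0.265 with an estimated correlation), and 6 of them passed when adjusted over the list alone, against 1 over all genes tested. Of 32 genes of the 26S proteasome 31 were above WT (median 0.14), with Psma5 at 0.34. The adjusted p was 2.08e-07 by camera and 0.373 with an estimated correlation. Reads in no annotated gene made up 9.83% and 7.42% of the Psmb11-deficient and 10.02% and 10.8% of the WT libraries. Whether this difference moved the list was not tested. Psmb5, the subunit of the ordinary proteasome whose place Psmb11 takes, was at 36.7 CPM against 31.7 CPM (log2 fold change 0.21, adjusted p = 0.458) and at 40.8 CPM against 36.3 CPM in mTEC hi (0.18, adjusted p = 1). The cell cycle genes were above WT in 14 of 16 cases (median 0.22, adjusted p = 0.000404; adjusted p = 0.455 with an estimated correlation). Their list mean was 2.95 and 2.78 in the Psmb11-deficient libraries and 2.79 and 2.48 in the WT libraries. The call was lost without WT replicate 3, the lowest of these (median 0.11, adjusted p = 0.188), and without Psmb11-deficient replicate 1, the highest (median 0.12, adjusted p = 0.0561). Erythroid genes (adjusted p = 8.42e-08) and B cell genes (5 of 6 above, adjusted p = 0.000648) passed too, both at an adjusted p = 0.265 with an estimated correlation. Apart from the B cell gene Cd79b (12 CPM over all mTEC lo libraries), these are genes with few reads in mTEC lo. The summed level of the erythroid list was 2.84 and 4.96 CPM in the Psmb11-deficient and 1.29 and 2.10 CPM in the WT libraries. The erythroid list mean was 0.52 and 0.77 in the Psmb11-deficient and 0.21 and 0.35 in the WT libraries. With conflicting labels it was 0.51 under the WT title and 0.29 under the knockout title. The summed level of the B cell list overlapped between the genotypes (15.01 and 15.04 CPM against 15.37 and 13.22 CPM). NRF2 and oxidative stress (9 of 11 above, adjusted p = 0.013, Prdx1 at 0.31) and chemokines (8 of 12 above, adjusted p = 0.0322, Ccl22 at 0.71) were at an adjusted p = 0.455 and 0.265 with an estimated correlation. The cTEC list (7 of 10 below, adjusted p = 0.00191; adjusted p = 0.265 with an estimated correlation) missed the threshold without Psmb11 (adjusted p = 0.219). The other lists had adjusted p of 0.0741 (Aire-dependent antigens) or more. With each of the 8 libraries left out in turn, the thymocyte, heat shock, 26S proteasome and erythroid lists passed every time. The B cell list missed the threshold without WT replicate 3 (adjusted p = 0.0845), and the NRF2, chemokine and cTEC lists missed it in 2 or 3 of the 8 fits. In 6 of these fits 1 to 3 lists passed that had not passed with all libraries. Within title number 2 the difference of the list mean was 0.39 for thymocyte genes and -0.27 for heat shock genes.

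**Figure D4:**
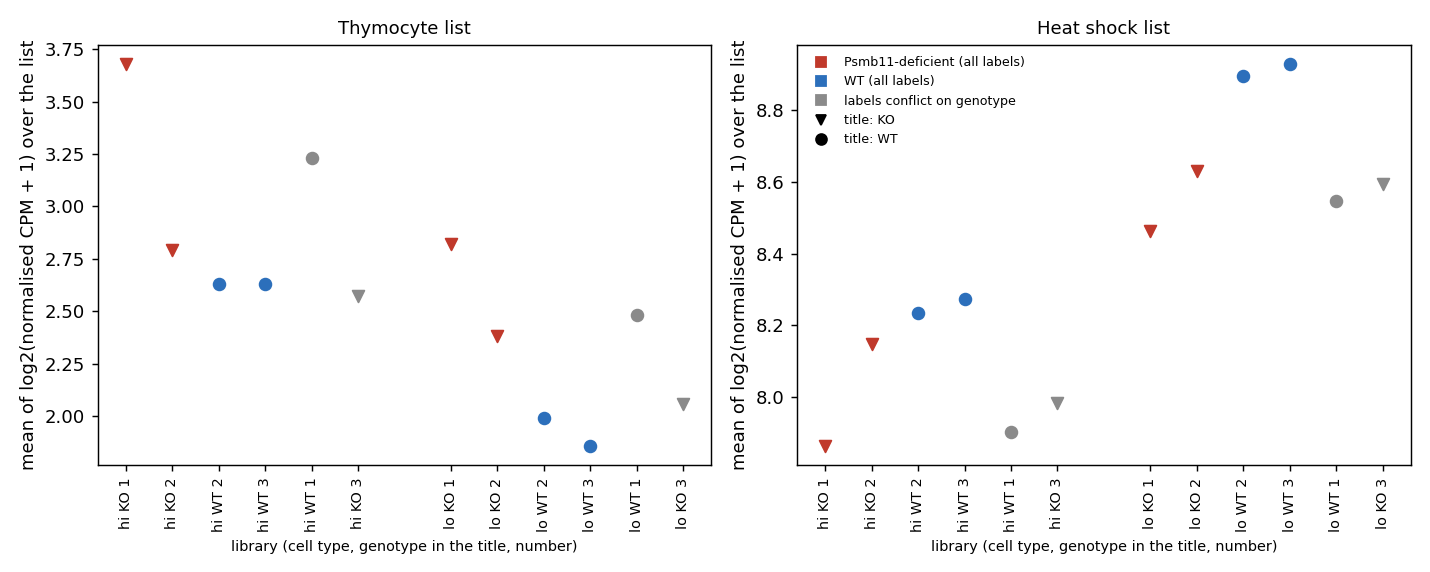
Mean of log2(normalised CPM + 1) over the thymocyte list and over the heat shock list (vertical axes, not starting at 0) in each library (horizontal axes). Each point is 1 library; in mTEC lo the thymocyte mean over the libraries numbered 1, 2 and 3 in the title was 2.65, 2.19 and 1.96, and the heat shock mean was 8.50, 8.76 and 8.76.

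Whether the loss of Psmb11 acts differently in mTEC hi and mTEC lo was tested as an interaction. By edgeR no gene of 26642 passed. The lowest p-values were those of Retnlg (adjusted p = 0.106), Hba-a1 (0.311), Myoc (0.723), Hbb-bt (0.821) and Reg3b (0.821). Psmb11 fell in both cell types. At an unadjusted p under 0.05 there were 1174 genes (4.41%), and DESeq2 called 9. Without Psmb11-deficient mTEC lo replicate 1 the edgeR count was 49, and without replicate 2 it was 14. Without WT mTEC lo replicates 2 and 3, each in turn, it was 5 and 6.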

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

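The tests on the title numbers, on tissue dissociation, on hemoglobin against Alas2, on macrophage transcripts taken separately and on Ptprc and Cd79b for B cells, and the other splits of the libraries, were chosen only after the result was seen. Of the 12 libraries split into 6 and 6 in 100 ways, the real split included, 1 gave as many genes as mTEC hi against mTEC lo (19649). The highest of the others gave 0. Each of the others mixes both cell types, so their count follows from the difference between the cell types, and no conclusion is drawn from it.

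Of 180 groups of 6 libraries examined, 7 held a library far from the others, where chance gives about 9. In mTEC hi, Gas1 was at 20.7 CPM in Psmb11-deficient replicate 1, with the others between 15.1 CPM and 16.9 CPM. Srxn1, an oxidative stress gene, was at 192 CPM in Psmb11-deficient mTEC hi replicate 2 (others 172 CPM to 179 CPM) and at 41.4 CPM in Psmb11-deficient mTEC lo replicate 2 (others 33 CPM to 35.8 CPM). The B cell gene Ms4a1 was at 3.32 CPM in Psmb11-deficient mTEC hi replicate 2 (others 4.3 CPM to 4.85 CPM). The mean of log2(CPM + 1) over the endothelial list was 2.9 in the mTEC hi library titled WT replicate 1 (others 2.34 to 2.48). Ackr4 was at 45 CPM in the mTEC lo library titled knockout replicate 3 (others 53.7 CPM to 56.9 CPM). The mean over the cell cycle list was 2.48 in WT mTEC lo replicate 3 (others 2.78 to 2.95).

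The effect of genotype differed between mTEC hi and mTEC lo by camera for 3 lists: cell cycle (adjusted p = 0.0285), B cell (adjusted p = 0.000149) and erythroid (adjusted p = 7.93e-08). With each of the 8 libraries left out in turn, erythroid passed every time. Cell cycle missed the threshold in 4 of the 8 fits (adjusted p 0.211 to 0.712), most clearly without WT mTEC lo replicate 3, the library far from the others above, and B cell missed it without that library (adjusted p = 0.089). In 7 of the 8 fits 1 to 4 lists passed that had not passed with all libraries, thymocyte (adjusted p = 2.21e-08) and heat shock (adjusted p = 2.6e-05) among them without Psmb11-deficient mTEC hi replicate 1. With an estimated correlation the camera adjusted p of the cell cycle, B cell and erythroid lists was 0.79, 0.318 and 0.318. Apart from Cd79b (12 CPM), the B cell and erythroid genes had few reads in mTEC lo. The summed level of the 2 lists over all 6 mTEC lo libraries was 13.5 ± 2.06 CPM and 2.64 ± 1.30 CPM. By title, the erythroid list mean in mTEC lo was 0.52 under knockout and 0.51 under WT in number 1. It was 0.77 and 0.21 in number 2, and reversed in number 3, at 0.29 and 0.35. Numbers 1 and 3 use the libraries whose labels conflict.

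Thymocyte genes were higher in the Psmb11-deficient libraries of both cell types, and RNA carried over from thymocytes may contribute: over 13 other T lineage transcripts the median log2 fold change was 0.608 in mTEC hi and 0.562 in mTEC lo, with 12 and 11 of them above WT. Ptprc was at 20.6 CPM against 13.4 CPM in WT in mTEC hi, but at 26.5 CPM against 25.6 CPM in mTEC lo. Trbc2 was at 13.2 CPM against 5.86 CPM and at 14.1 CPM against 8.11 CPM. Neither gene passed the threshold in either cell type. Gates of the sort other than MHC class II are not given in the sources used here. In the 8 libraries of undisputed genotype, a difference between the title numbers and an effect of genotype cannot be told apart. Among these, number 1 has no WT library and number 3 no Psmb11-deficient library. Within number 2 the list mean differed by 0.166 in mTEC hi and 0.392 in mTEC lo, against 0.608 and 0.678 over all. By title each number holds both genotypes, and Psmb11 followed the titles in all 12 libraries. Between the library titled knockout and that titled WT, the list mean differed by 0.453, 0.166 and -0.0588 in mTEC hi for numbers 1, 2 and 3. In mTEC lo it differed by 0.34, 0.392 and 0.199, and numbers 1 and 3 use the libraries whose labels conflict. Read this way, the mTEC hi difference stayed under 0.608 in each number and was reversed in number 3.

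Heat shock genes were lower in the Psmb11-deficient libraries of both cell types, and an effect of the loss of Psmb11 stays open and untested. Stress of tissue dissociation stays open in mTEC hi, where the immediate early genes had a median of -0.179 against -0.204, but without Psmb11-deficient replicate 1 the medians were 0.0146 and -0.103. In mTEC lo the immediate early genes fell less: the medians were -0.058 (SD 0.105 over the members) and -0.357 (SD 0.267), a gap of 0.299. The gap exceeds the SD of 0.105. That SD is a spread over genes and not over libraries, so dissociation stress stays open in mTEC lo too. In the libraries of undisputed genotype, a difference between the title numbers cannot be told apart from genotype, for the same reason as above. Within number 2 the list mean differed by -0.088 in mTEC hi and -0.266 in mTEC lo, against -0.25 and -0.367 over all. By title the difference was -0.0388, -0.088 and -0.293 in mTEC hi and -0.0844, -0.266 and -0.337 in mTEC lo for numbers 1, 2 and 3, with the libraries of conflicting labels in numbers 1 and 3.

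Marker genes of B cells, dendritic cells, macrophages and red cells were higher in mTEC hi than in mTEC lo. The tables argue against red cells, since summed hemoglobin was 0.446 times Alas2 (0.322 to 0.593 over the 6 libraries). A general rise of genes silent in mTEC lo stays open. Of 8570 genes under 1 CPM in mTEC lo, 6153 rose and 537 fell past the threshold. These genes were picked for a low mTEC lo level, after a filter that a gene could pass by its mTEC hi level alone. The choice itself favours rises, so no conclusion is drawn from these counts. The median of the 15 markers under 1 CPM in mTEC lo (3.74) lay at percentile 99.7 of 10000 random sets (median 1.55), beyond the bound set beforehand. Those sets were matched on the mTEC lo level alone, so the larger rise of the markers cannot decide it. For macrophages the tests point apart. Lyz2 and Tyrobp together were 21.4 times Adgre1, as macrophage RNA could give, but Lyz2 made up 425 of the 428 CPM. The median of Tyrobp, Fcer1g, C1qa, C1qb and C1qc was only 0.449 times Adgre1 (0.365 to 0.563). No macrophages were measured here, so the ratios that their RNA would bring were assumed. RNA from B cells stays open: Ighm and Igkc together were 3.15 times Blk, between the bounds set beforehand, although both were lower in mTEC hi than in mTEC lo (32.5 CPM against 50.5 CPM and 13.2 CPM against 36.5 CPM), as was the leukocyte gene Ptprc (17.1 CPM against 24.4 CPM), and Cd79b was at 15.1 CPM against 12 CPM, which go against such RNA but start from levels in mTEC lo that would hide a small share.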

How the results depend on the processing

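Scaling by library size alone, leaving out the libraries of title number 1, leaving out each library for the lists between genotypes, and the replicate block within each cell type were chosen after the data were seen. Of the counts for mTEC hi against mTEC lo, only that against a minimum change of 1.5-fold, 12958, lay beyond 1.5 times the main count, by construction of that test; leaving out each library gave 19337 to 20129. The difference in detected genes kept its direction under other read minimums and without thinning (3577 to 7068) and was 5716 to 5840 when each library was left out. Of 60 genes named there and run under up to 5 alternatives, Emcn lost its call under RSEM counts and under library size alone. Reversed in sign, each past the threshold in neither fit and with the cause not tested, were Psmb11 in mTEC hi against mTEC lo (0.0086 with RSEM counts, 0.17 with library size alone) and, in mTEC lo between genotypes, Plcb2 (0.017) and Tek (0.021) with genotype from the source name and Csf1r (0.055) with RSEM counts.

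For Psmb11-deficient against WT the cause of each change was not tested. In mTEC hi (1 gene) the count was 42 with no filter, 3 with RSEM counts, 3 with DESeq2, 0 with genotype from the source name, 2 with this cell type fitted alone and 0 to 2 when each library was left out. In mTEC lo (4 genes) it was 660 with no filter, 158 with DESeq2, 2 with genotype from the source name, 1 with this cell type fitted alone, 258 without the libraries of title number 1 and 1 to 323 when each library was left out. For the interaction (0 genes) it was 141 with no filter, 2 with RSEM counts, 9 with DESeq2, 36 without the libraries of title number 1 and 0 to 49 when each library was left out. Psmb11 lost its call in both cell types with genotype from the source name. Where a group kept 1 library, it was assumed to vary like the others. The lists past the threshold fell from 13 to 5 with an estimated correlation and rose to 22 with fry for mTEC hi against mTEC lo. They fell to 0 with an estimated correlation and 0 with fry for the genotypes in both cell types. With genotype from the source name 7 lists passed in mTEC hi, and with genotype from the title 14 passed in mTEC lo. When each library was left out 3 to 11 lists passed in mTEC hi (11 with all) and 8 to 10 in mTEC lo (9 with all). At this size and depth the fits recovered 88% and 90% of simulated 2-fold changes in mTEC hi and mTEC lo. Of 1.5-fold changes they recovered 40% and 50%, so many changes under 2-fold would be missed. The simulated changes were in genes of at least 2 CPM, and many genes changed at once, which eases the adjusted threshold. Where few genes change, 2-fold changes could be missed more often than in the simulation.

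Libraries with matching titles were checked for pairing: the correlations of their deviations ranged from -0.00331 to 0.293 between cell types and from -0.107 to 0.251 between genotypes, which does not establish pairs. With genotype from the title 3 genes and 14 lists passed in mTEC lo and no gene for the interaction. With the title number added as a replicate block 12 genes and 15 lists passed in mTEC lo, Hsph1 among them (-0.73, adjusted p = 0.00459). With genotype from the title and a replicate block within each cell type 67 genes passed in mTEC lo and 4 for the interaction.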

Other observations

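The symbol families, the processed pseudogenes and the library summaries were examined only after the data were seen. Gene families named by symbol were tested as groups in mTEC hi against mTEC lo, 121 families of at least 15 measured genes, and 19 passed upward and 12 downward by camera. All 26 kallikrein genes (Klk) rose, with a median log2 fold change of 3.73 (adjusted p = 1.6e-08; adjusted p = 0.183 with an estimated correlation). Of 135 olfactory receptor genes (Olfr) 125 rose and 2 fell (median 5.94, adjusted p = 0.000381; adjusted p = 0.462 with an estimated correlation), to a summed level of 123 CPM against 42 CPM. Of 88 cytochrome P450 genes (Cyp) 70 rose and 11 fell (median 3.57, adjusted p = 0.00285; adjusted p = 0.183 with an estimated correlation). Of 54 keratin genes (Krt) 40 rose and 7 fell (median 3.02, adjusted p = 0.00142; adjusted p = 0.381 with an estimated correlation), while their summed level was lower in mTEC hi (6510 CPM against 13900 CPM). Genes with Tbx symbols (13 of 15 rose, median 4.63) and carboxylesterases (Ces, 17 of 18 rose, median 3.22) passed camera too, at an adjusted p = 0.145 and 0.323 with an estimated correlation. Families were formed by the symbol alone, so the Tbx group need not hold only T-box transcription factors. No family held with an estimated correlation.

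In the other direction, 31 of 32 taste receptor genes (Tas) fell in mTEC hi (median -3.02, adjusted p = 0.000206; adjusted p = 0.488 with an estimated correlation), from 148 CPM to 31.8 CPM summed. Of 22 protocadherin beta genes (Pcdhb) 21 fell and none rose (median -2.26, adjusted p = 0.000206; adjusted p = 0.145 with an estimated correlation).

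Among 1690 processed pseudogenes tested between the genotypes by edgeR, 110 were above and 19 below WT at an unadjusted p under 0.05 in mTEC hi. In mTEC lo 32 were above and 106 below. Over all genes tested, 442 were above and 476 below in mTEC hi, and 1411 above and 1599 below in mTEC lo. Mitochondrial reads made up 1.82 ± 0.0787% of mTEC hi and 2.60 ± 0.367% of mTEC lo libraries (SD, n = 6 each; exact two-sided permutation p = 0.00216).

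A segment of another strain around the targeted locus was tested, as it may carry its own differences. Within 5 Mb of Psmb11, 10 of 201 genes (4.98%) had an unadjusted p under 0.05 in mTEC hi, against 3.44% of all genes, and 12.4% against 11.3% in mTEC lo, with none past the adjusted threshold. These values lie between the bounds set beforehand, so such a segment stays open.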
